A study of Arabidopsis thaliana with 6 samples.

How the data were processed

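Transcript levels were measured in whole Arabidopsis thaliana seedlings of the Col-0 background, collected at 2 weeks after growth on MS plates under 16 h light and 8 h dark at 22 °C. The labels give 3 genotypes, wild type, nar1-4 and nbp35-3, with 2 arrays each, and the series' design text calls the arrays of a genotype biological replicates. Each sample was placed by its title. The source name of the nbp35 samples gives another allele number, nbp35-4, than their title and genotype, and the title was followed. The labels do not say what the sign "/-" after an allele means. Per the labels' protocols, total RNA was extracted with a plant RNA column kit, and biotin-labelled cRNA was made from 250 ng RNA, or from 200 ng for 3 samples that are named by codes the labels do not tie to genotypes.

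The authors' deposited table holds log2 expression values of 22810 probe sets on 6 arrays. Per the submitters' processing notes the values come from RMA, which corrects background, normalizes the arrays together by quantiles and summarises probes into probe sets, so that absolute differences in RNA amount between samples are removed. The RMA software version is not given in the sources used here. The values were used as deposited, with array medians of 5.70 to 5.83, and 0 value columns were left without a sample. Probe set intensities before normalization were not used here, so signal over background was not measured, and the number of arrays limits the precision.

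Probe sets were named from a table of the array's platform annotation, and symbols were updated through the locus in a RefSeq gene table of assembly TAIR10.1. Of 22746 probe sets left after 64 Affymetrix control probe sets were set aside, 13513 (59.41%) named 1 gene, 503 several and 8730 none. Of those naming 1 gene, 13436 matched a locus of the RefSeq table, and 13355 genes were named. No gene was named from a probe set with several names.

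Differences were tested on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with 1 mean per genotype over all 6 arrays, which leaves 3 residual degrees of freedom, and with Benjamini-Hochberg adjustment over 22746 probe sets at a threshold of 0.05. The comparisons were nar1-4 with wild type, nbp35-3 with wild type and nbp35-3 with nar1-4. The same fit with the replicate number as a block (2 residual degrees of freedom) was an alternative, and is given for the counts of calls and the lists called because the arrays separate by that number. The labels do not say what a number shares, so it was treated as a possible batch, and differences within each number are printed for part of the genes named. Unless the block is named, each SE printed comes from the fit without it and so includes the difference between the numbers. Deviations from the genotype means correlated between arrays of the same number at 0.814 for wild type and nar1-4, 0.694 for wild type and nbp35-3, and 0.674 for nar1-4 and nbp35-3.

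The named genes were fixed by rule before the data were examined: with fewer than 3 probe sets past the threshold, the 5 with the smallest p in each direction among probe sets naming 1 gene, plus at most 2 members of each gene list with the smallest p. NAR1 and NBP35 were always to be named.

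Gene lists were also written before the data were examined. They covered cytosolic Fe-S cluster assembly, organellar Fe-S cluster assembly, cytosolic and nuclear Fe-S proteins, DNA damage response, oxidative stress response, antioxidant enzymes, iron deficiency, iron storage, DNA methylation machinery, imprinted and methylation-silenced genes, and photosynthesis. The others were S phase, G2 and M phase, salicylic acid and defence, jasmonate, flavonoid biosynthesis, heat shock, abscisic acid with drought and cold, senescence, root markers, flowering, and embryo and seed. The lists for photosynthesis, senescence, roots, flowering, and embryo and seed stand for organs or stages that whole seedlings could hold in different shares. A locus was a member only where the gene table pairs it with a written name. Of 476 members in 22 lists, 462 were matched, 53 were measured by a probe set naming 1 gene, and 14 were left out for want of a name match, 11 of which were measured. The lists for iron storage and for DNA methylation machinery had 0 measured members, and 11 lists had at least 3. Lists were tested with camera in limma at a preset correlation of 0.01, with 1 probe set per gene, and Benjamini-Hochberg adjustment over the 20 lists with a measured member. Each call was repeated with an estimated correlation and with fry.

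The alternatives fixed beforehand were a trended or robust prior, filters on dim probe sets, median centring, quantile normalization, fits of 2 genotypes, array weights, the replicate block, other thresholds, probe sets naming 1 gene, the mean of a gene's probe sets, and leaving out each array. Added after the data were seen were counts within each number, list membership by locus alone, lists of at least 3 members, correlations without a shared array, and the block combined with other settings. Both fits were tested on simulated data in which 200 of 22746 probe sets were changed in nar1-4. Without the block 0% were recovered at a log2 change of 1, 48.5% at 2, 71.5% at 3 and 90.5% at 4. With the block the shares were 0%, 76%, 88.5% and 94%. These shares hold for the simulated noise and for 200 changed probe sets, and do not give the share of real differences that would be found.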

Results

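NAR1 and NBP35 belong to the machinery that assembles iron-sulphur (Fe-S) clusters in the cytosol and passes them to cytosolic and nuclear proteins, and the series title describes both mutants as deficient in this assembly. Expression of 22746 probe sets was compared on 6 arrays, 2 each for wild-type, nar1-4 and nbp35-3 whole seedlings of 2 weeks. Neither mutated gene could be followed, since 0 probe sets named NAR1 (AT4G16440) and 0 named NBP35 (AT5G50960), so the genotype labels were not checked against transcript level.

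The arrays separated by replicate number, and the 2 arrays of a genotype did not group together. COR27, a cold- and clock-regulated gene, stood at a mean of 9.14 over the 3 arrays of number 1 and 3.96 over those of number 2, and BHLH101, a transcription factor of the iron deficiency response, at 3.37 and 6.95. The first principal component took 69.9% of the variance and divided the numbers, and the second, with 11.5%, set nbp35-3 replicate 2 at 29.72 apart from the other arrays, which lay between -20.47 and 9.88. Arrays of different genotypes and the same number correlated at 0.9873 to 0.9943 across probe sets, while the 2 arrays of 1 genotype correlated at 0.9679 to 0.9698. Arrays that shared neither genotype nor number correlated at 0.9627 to 0.9772, a range that holds the values within a genotype. The highest of these was nbp35-3 replicate 2 with nar1-4 replicate 1, above nbp35-3 replicate 2 with nbp35-3 replicate 1 (0.9698). The 18 hybridisation spike probe sets averaged 9.19 in number 1 and 10.65 in number 2. The 3′ minus 5′ difference of the actin control, a measure of RNA quality and labelling, was 3.34 to 3.82 on the 6 arrays.

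**Figure D1:**
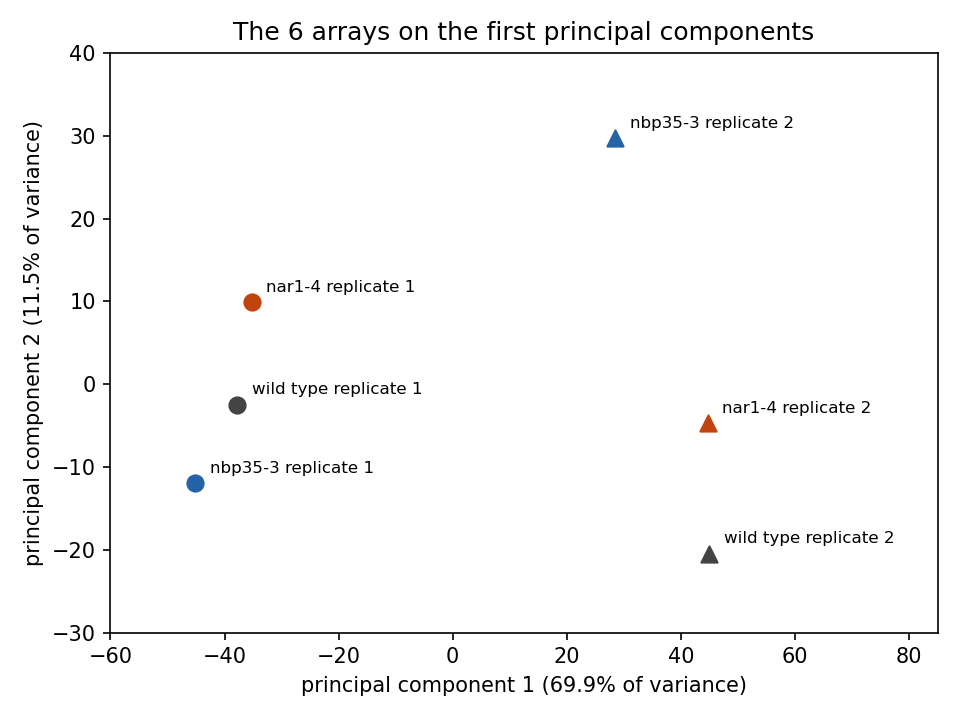
Each point is 1 array on the first (horizontal axis) and second (vertical axis) principal component of the log2 values, with circles for replicate 1 and triangles for replicate 2 of each genotype. The circles lie between -45.19 and -35.25 and the triangles between 28.51 and 45.02 on the first component, and nbp35-3 replicate 2 lies highest on the second.

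Seedlings of nar1-4 were compared with wild type to ask which transcripts differed when this part of the assembly pathway was impaired. The named transcript furthest above wild type was AT2G04050, at 6.46 ± 0.07 (SD, n = 2) in nar1-4 and 3.24 ± 0.38 in wild type, a 9.3-fold difference (log2 3.22 ± 0.29, SE), with 3.54 within number 1 and 2.90 within number 2. The wild-type mean of AT2G04050 lay under the first quartile of every array, so the fold is measured from a low baseline. AT2G04050 had been written into the oxidative stress list as DTX3, a toxin efflux transporter, although the gene table does not pair that name with the locus. AT2G21640, written into the same list as UPOX, a gene induced by oxidative stress, was 3.04-fold higher (log2 1.61 ± 0.28), and AT2G41730 was 2.35-fold higher (log2 1.23 ± 0.21). The named transcript furthest below was AT5G14940, at 3.70 ± 0.10 in nar1-4 and 6.38 ± 0.53 in wild type (log2 -2.68 ± 0.38), with -2.99 within number 1 and -2.37 within number 2. AT2G43590, of the chitinase family, differed by -1.16 ± 0.18 on the log2 scale.

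Smaller differences filled the rest of the named set. AT2G25735 stood 0.86 and YAB5, a YABBY transcription factor of leaf polarity, 0.75 above wild type on the log2 scale, and each was higher in both numbers. APS4, an ATP sulfurylase of sulphate assimilation, differed by -0.83 ± 0.16, with -0.99 and -0.68 within numbers 1 and 2. AT2G21045 differed by -0.73 and AT3G22850 by -0.54.

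None of these genes passed the limma test. With Benjamini-Hochberg adjustment 0 probe sets were called, the smallest adjusted p was 1, and 196 probe sets had an unadjusted p under 0.05 (84 higher, 112 lower) where chance gives 1137. Without the block the difference between the numbers enters the residual spread and raises p. Here and in the other comparisons, counts under 1137 are therefore no evidence that genotypes are alike. With the replicate block 0 were called, 1009 had an unadjusted p under 0.05, and the smallest adjusted p was 0.155, for AT2G04050, followed by 0.197 for AT5G14940. Some probe sets passed with the block and an nbp35-3 array left out, AT2G04050 and AT5G14940 among them, an alternative chosen after the data were seen. That fit leaves nbp35-3 a single array and 1 residual degree of freedom, so its calls are not counted here.

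**Figure D2:**
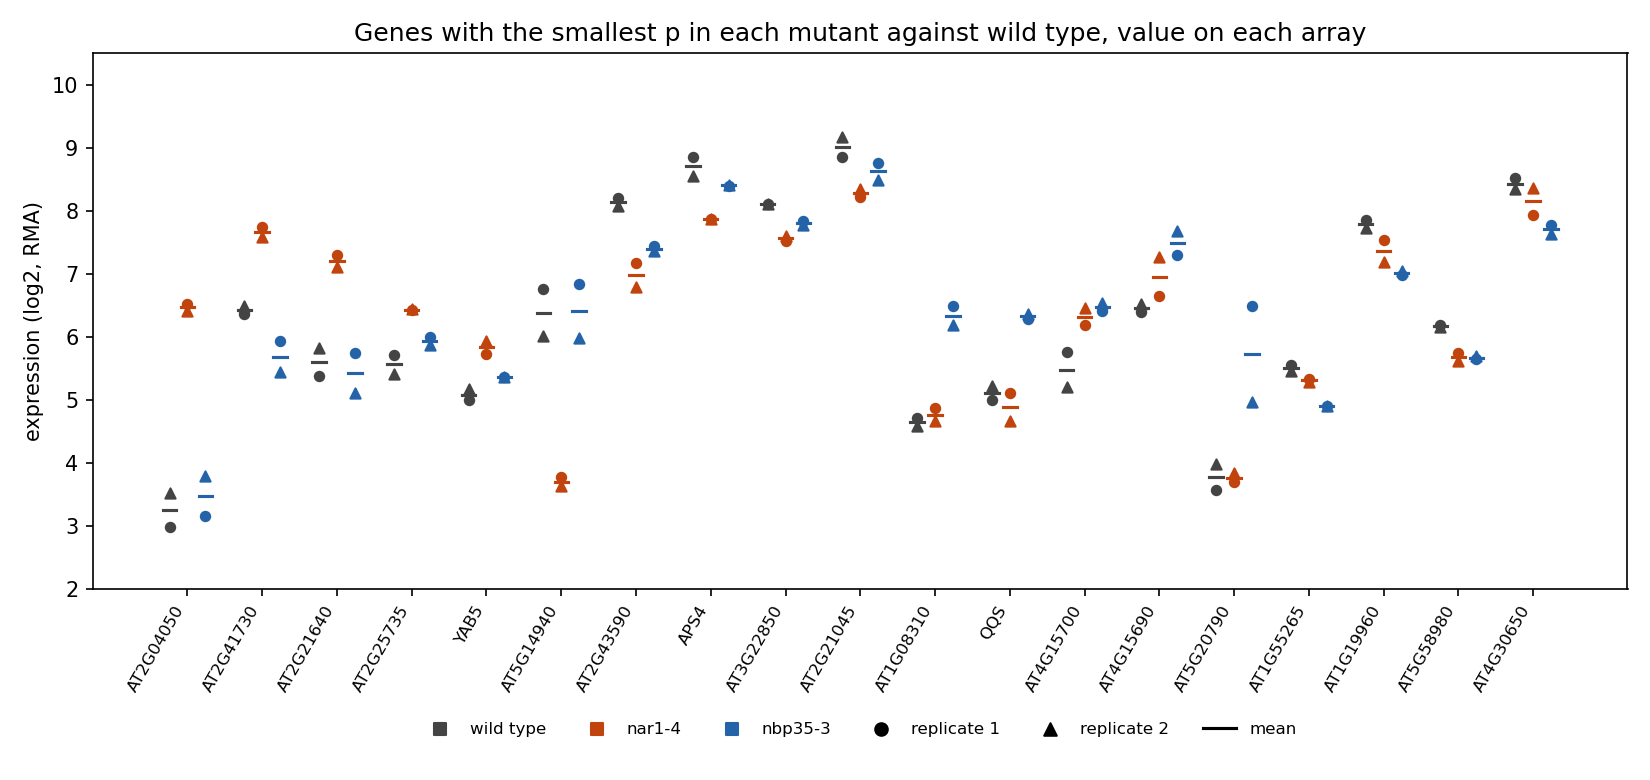
Log2 expression (vertical axis) of the genes with the smallest p in each mutant against wild type (horizontal axis), with 1 symbol per array and a bar at each genotype's mean of 2 arrays. The 2 nar1-4 arrays lie around 6.46 for AT2G04050, where wild type averages 3.24 and nbp35-3 averages 3.47, and around 3.70 for AT5G14940, where the other genotypes average 6.38 and 6.41.

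Differences of at least 2-fold recurred between the numbers in nar1-4. Within both numbers, 31 probe sets were at least 2-fold from wild type in the same direction (21 higher, 10 lower) and 4 in opposite directions. Independent numbers would give 0.7 of each if all probe sets were equally likely to differ. Probe sets with a wide spread can exceed such a figure in both directions. In this and the other comparisons the same and opposite counts are therefore best set against each other. Of the 31, 18 named 1 gene, 11 higher and 7 lower. Across probe sets, which are not independent replicates, the nar1-4 differences of number 1 and number 2 correlated at 0.214 (Spearman 0.157).

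**Figure D3:**
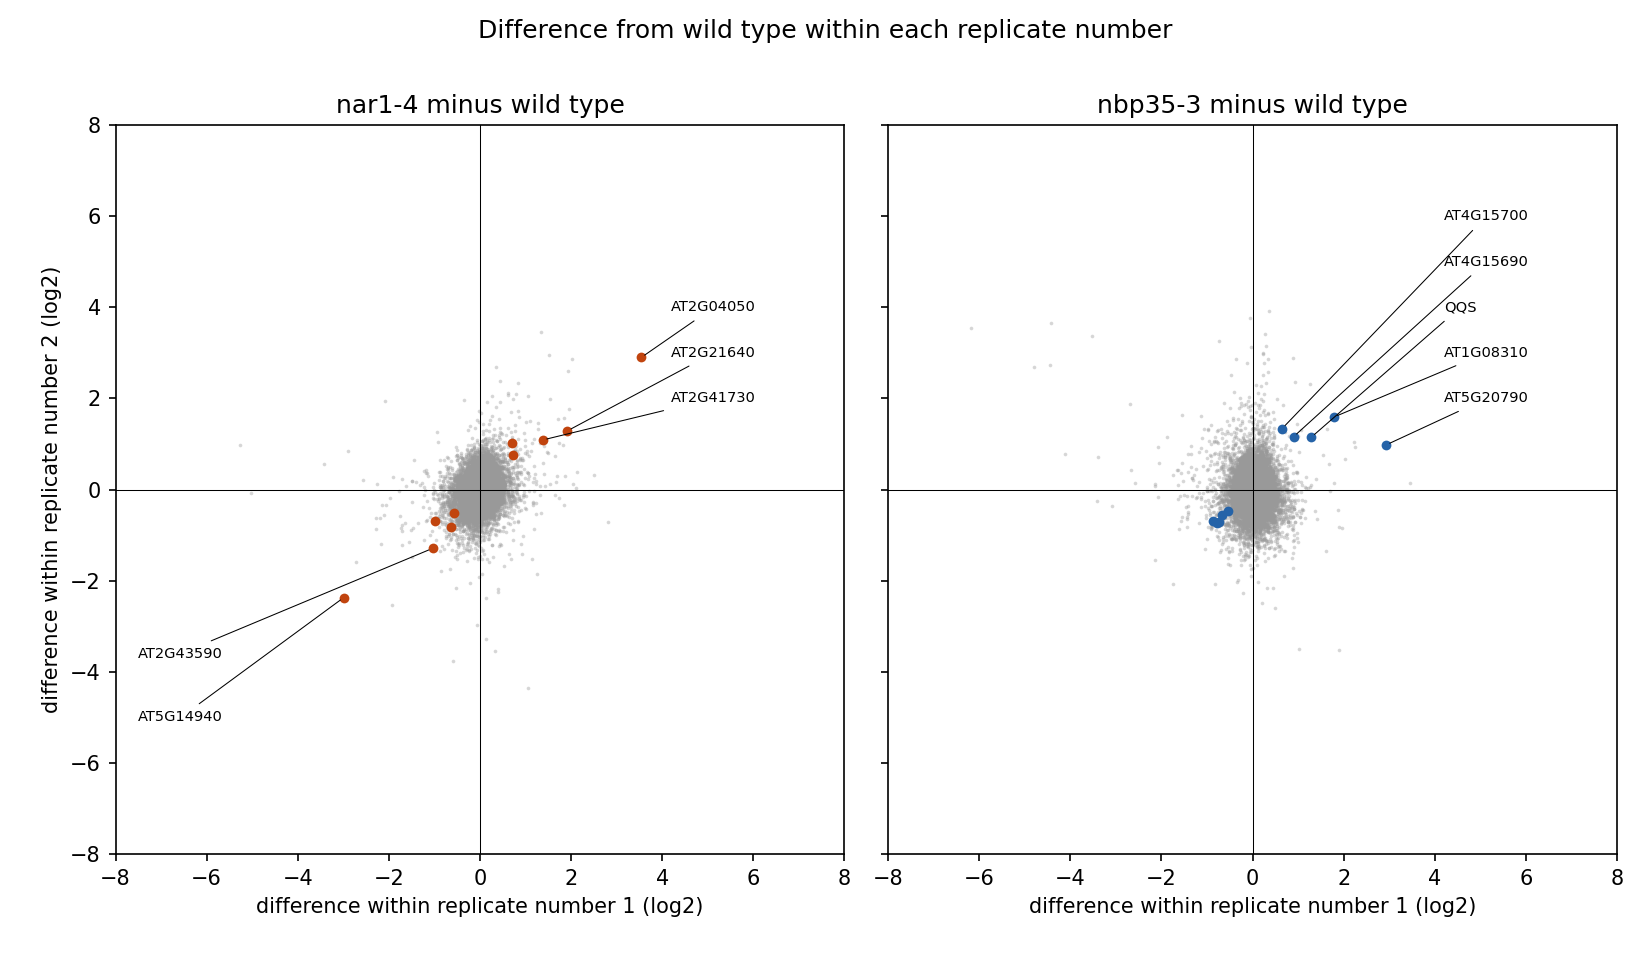
Each grey point is 1 probe set, placed by its log2 difference from wild type within replicate number 1 (horizontal axis) and within number 2 (vertical axis), for nar1-4 on the left and nbp35-3 on the right. Coloured points are the genes with the smallest p in that comparison, and the 2 axes correlate at 0.214 in nar1-4 and -0.046 in nbp35-3.

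Among the lists in nar1-4, 1 was called by camera, that for flowering, whose only measured member was AGL24, a MADS-box promoter of flowering. AGL24 stood at 4.43 in nar1-4 and 5.17 in wild type (log2 -0.74 ± 0.20), with -0.41 and -1.07 within numbers 1 and 2. The camera adjusted p was 0.0103, and adjusted p = 0.546 with an estimated correlation and 0.125 with the replicate block, so the call was lost in both. Adjustment over a list with 1 measured gene changes nothing, so the limma p of AGL24 over the list alone, 0.0126, is unadjusted. Over all probe sets 0 members of any list passed.

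Camera called 0 lists of the assembly pathway and its clients in nar1-4, but few of their members were matched by name and measured, so the lists as a whole were not tested. AT3G02280, written as the electron donor ATR3, stood for the 11 genes of the cytosolic assembly list and differed by 0.10 (camera adjusted p = 0.595). Of 26 genes of organellar assembly 4 were measured, with SUFE2 at -0.34 (-0.12 and -0.57 within numbers 1 and 2), the scaffold ISU1 at 0.19, HCF101 at 0.18 and CPNIFS at 0.07 (median 0.13, adjusted p = 0.476). The DNA demethylase DME, for a list of 22 Fe-S proteins, differed by 0.11 (adjusted p = 0.533), ATLIG4, for 27 genes of DNA damage, by -0.11 (0.497) and MPC, for 14 imprinted or silenced genes, by 0.26 (0.13). MPC stood at only 2.81 in wild type and 3.07 in nar1-4, under the first quartile of every array.

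Stress and iron lists in nar1-4 were uneven among their members. The oxidative stress list had a median of 0.20 over 4 members, from the zinc finger gene STZ at 0.53 to the glutathione transferase GSTU22 at -0.46 (adjusted p = 0.534), and the antioxidant list a median of 0.04 over 5, with the ascorbate peroxidases TAPX at 0.11 and SAPX at -0.14 (adjusted p = 0.806). Of 3 iron deficiency genes, BHLH101 differed by 1.35 ± 2.03, an SE that holds the gap between the numbers and was 0.49 with the replicate block. BHLH101 was 0.62 and 2.09 higher within numbers 1 and 2. PYE differed by 0.41 and AT3G13610, written as F6'H1, by -0.39 (median 0.41, mean 0.46, camera adjusted p = 0.534). Heat shock genes had a median of -0.47, with HSA32 at -0.47 and ATHSP22.0 at -0.49 (adjusted p = 0.13), and the cold-induced COR15A and COR15B differed by -1.41 and -0.29 in the abscisic acid, drought and cold list (adjusted p = 0.13). GRX480, a defence-linked glutaredoxin and the only measured gene of its list, differed by -0.82 ± 0.33 (camera adjusted p = 0.0865), with -0.13 and -1.51 within numbers 1 and 2. With the replicate block its limma p was 0.0418, which is unadjusted since no other gene of the list was measured. The defensin PDF1.2b differed by -0.93 (0.40 and -2.25 within numbers 1 and 2) and THI2.1 by -0.13 in the jasmonate list (adjusted p = 0.476), and DFR, an enzyme of anthocyanin synthesis, by -1.18 (-2.58 and 0.21 within the numbers) in the flavonoid list (median -0.36, adjusted p = 0.13).

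Lists for growth, organs and stages in nar1-4 gave 0 further calls. WRKY53, a senescence regulator, stood at 3.99 against 3.20 (log2 0.80 ± 0.25, with 0.95 and 0.64 within the numbers) in a list with a median of 0.35 (adjusted p = 0.13). WRKY53 in wild type lay under the first quartile of every array. Its p adjusted over the list alone was 0.0707, and 0.027 with the replicate block. The 6 photosynthesis genes had a median of 0.08, with LHCB4.1 at 0.10 (adjusted p = 0.476). The replication genes PRL and ICU2 differed by 0.17 and -0.16, ICU2 by 0.29 and -0.60 within the numbers (adjusted p = 0.806), and the mitotic kinases AUR1 and AUR2 by -0.21 and -0.10 (adjusted p = 0.401). Root markers had a median of -0.06, with PYK10 at -0.14 and EXPA18 at 0.15 (adjusted p = 0.806), and the seed genes M17 and M10 differed by 0.21 and 0.07 (adjusted p = 0.595). M17 and M10 stood at only 2.29 and 2.62 in wild type, and in nar1-4 too lay under the first quartile of the arrays.

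The nbp35-3 seedlings were compared with wild type in the same way. The transcript with the smallest p was AT1G08310, at 6.33 ± 0.21 (SD, n = 2) in nbp35-3 and 4.64 ± 0.08 in wild type, 3.22-fold higher (log2 1.69 ± 0.17, SE), with 1.78 within number 1 and 1.59 within number 2. QQS, a gene named for its effect on leaf starch, was 2.33-fold higher (log2 1.22 ± 0.20), with 1.29 and 1.15. The glutaredoxin genes AT4G15690 and AT4G15700 were 2.04-fold and 1.99-fold higher, each in both numbers. AT5G20790 had a mean 1.96 ± 0.52 higher, but 2.93 within number 1 and 0.98 within number 2.

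The 5 lower means with the smallest p in nbp35-3 differed by less than 1 log2 unit, although some others were lower by more. AT1G19960 differed by -0.78 ± 0.17, AT2G43590 by -0.75 ± 0.18, AT4G30650 by -0.72 ± 0.19, AT1G55265 by -0.61 ± 0.13 and AT5G58980 by -0.50 ± 0.13, each lower in both numbers. AT2G43590 was the only gene among the 5 with the smallest p in a direction in both mutants.

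Again 0 probe sets were called by limma with Benjamini-Hochberg adjustment, the smallest adjusted p was 1, and 139 had an unadjusted p under 0.05 (73 higher, 66 lower) against 1137 by chance. With the replicate block 0 were called, 1076 had an unadjusted p under 0.05 and the smallest adjusted p was 0.306, for AT1G08310. With the block, leaving out an nbp35-3 array gave calls whose number depended on which array was left out, each resting on a single nbp35-3 array. Within both numbers 9 probe sets were at least 2-fold from wild type in the same direction (6 higher, 3 lower) and 15 in opposite directions, where independent numbers would give 1.2 of each. The 4 of these 9 that named 1 gene were AT1G08310, QQS, AT4G15680 and DFR, of which AT4G15680 lay outside the naming rule and was singled out after its values were seen. The nbp35-3 differences of the 2 numbers correlated at -0.046 across probe sets (Spearman 0.010).

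Camera called 2 lists in nbp35-3, both lower. Of 22 genes in the abscisic acid, drought and cold list 3 were measured. COR15A stood at 7.05 against 8.77 in wild type (log2 -1.72 ± 0.63, with -3.08 and -0.35 within numbers 1 and 2), COR15B at 6.20 against 7.24 (log2 -1.04 ± 0.34, with -1.44 and -0.63), and the dehydrin gene COR47 differed by 0.07. The list's median was -1.04 (adjusted p = 0.0135, and adjusted p = 0.558 with an estimated correlation and 0.0549 with the replicate block). In the G2 and M phase list only AUR1 and AUR2 of 21 genes were measured, so neither list was tested as a whole. AUR1 and AUR2 differed by -0.41 ± 0.17 and -0.31 ± 0.29, each lower in both numbers (camera adjusted p = 0.0278, and adjusted p = 0.558 with an estimated correlation and 0.0549 with the block). Adjusted over the list alone, 0 members of these lists passed without the block, and with it 2 passed in the first list, the smallest at 0.0118, and 0 in the second.

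In the other 18 lists tested in nbp35-3 the camera adjusted p was 0.064 to 0.987, and 0 members passed when adjusted over the list alone. The oxidative stress list had a median of -0.32 (adjusted p = 0.064), with GSTU22 at -0.47, of which 0.01 came within number 1 and -0.96 within number 2, and GSTU25 at -0.34 (0.16 and -0.83). The flavonoid list had a median of -0.37 (adjusted p = 0.064), with DFR at -1.18 (-1.04 and -1.31 within the numbers) and UF3GT at -0.36. Replication genes had a median of -0.37, with PRL at -0.47 and ICU2 at -0.28 (0.54 and -1.09 within numbers 1 and 2), and the list's median was 0.15 and -0.89 within the numbers. AT3G02280 of cytosolic assembly differed by 0.09, and organellar assembly had a median of 0.15, with CPNIFS at 0.22 and ISU1 at 0.13. DME differed by -0.01, ATLIG4 by 0.08, MPC by 0.29, GRX480 by -0.37 and AGL24 by -0.31. The jasmonate list had a median of 0.16 while camera ranked it lower (adjusted p = 0.687), with PDF1.2 at 1.97 within number 1 and -0.83 within number 2. Medians were -0.06 for antioxidant enzymes, -0.22 for iron deficiency, 0.06 for photosynthesis, -0.12 for heat shock, -0.08 for senescence, 0.07 for root markers and 0.45 for the seed genes, and each of these except photosynthesis had opposite signs within the 2 numbers.

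The direct comparison of nbp35-3 with nar1-4 asked where the mutants differed from each other. AT2G04050 was lower in nbp35-3 by the largest margin of the named set (log2 -2.99 ± 0.29, SE, with -3.36 and -2.62 within numbers 1 and 2). The nbp35-3 mean stood at 3.47, near wild type and likewise under the first quartile of every array. AT5G14940 was 2.71 ± 0.38 higher in nbp35-3, where it again stood near wild type. AT2G41730 differed by -1.97 ± 0.21 and AT2G21640 by -1.78 ± 0.28, while AT1G08310 was 1.57 ± 0.17 and QQS 1.43 ± 0.20 higher in nbp35-3. AT3G43110 and AT4G16920 were 0.77 and 0.64 higher, and AT2G32020 and AT2G32220 differed by -0.74 and -0.61.

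Here too limma with Benjamini-Hochberg adjustment called 0 probe sets, with the smallest adjusted p at 1 and 217 probe sets with an unadjusted p under 0.05 (115 higher, 102 lower). The replicate block called 0, with 1263 at an unadjusted p under 0.05 and an adjusted p of 0.152 for AT2G04050, AT5G14940 and AT1G08310. Calls appeared with the block when an nbp35-3 array was left out, and again rested on a single array of that mutant. Within both numbers 30 probe sets were at least 2-fold apart in the same direction (8 higher, 22 lower in nbp35-3) and 32 in opposite directions, where independent numbers would give 2.4 of each.

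The oxidative stress list was the 1 list called between the mutants, lower in nbp35-3 with a median of -0.53 over 4 members. STZ differed by -0.60 ± 0.34 and GSTU25 by -0.58 ± 0.33, but GSTU25 by -0.03 within number 1 and -1.12 within number 2. The list's median was -0.01 within number 1 and -0.65 within number 2. The camera adjusted p was 0.0448, and adjusted p = 0.655 with an estimated correlation and 0.135 with the replicate block. In the other 19 lists tested the adjusted p was 0.134 to 0.906. Adjusted over the list alone 0 members passed, while with the block 1 passed in each of senescence (WRKY53, log2 -0.87 ± 0.25, 0.0179), S phase (PRL, -0.64 ± 0.27, 0.0343) and the abscisic acid, drought and cold list (COR15B, -0.75 ± 0.34, 0.0489). The flavonoid list had a median of 0.01 while camera ranked it lower (adjusted p = 0.906).

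Calls shared by both mutants numbered 0, and 19 probe sets had an unadjusted p under 0.05 in both limma contrasts in the same direction (5 higher, 14 lower). Independent lists of these sizes would share 0.6. Simulated unchanged genotypes, both compared with a common wild type, shared 62.1 on average. With the replicate block the shared number was 214, against 24 for independent lists and 422.6 in the simulation. Over all probe sets the log2 fold changes of the mutants correlated at 0.453 (Spearman 0.422), and simulated unchanged genotypes gave 0.501 on average (0.455 to 0.546 in 100 simulations). The covariance was 0.0216 against 0.0229 simulated, a difference of -0.0013. The shared counts, the correlation and the covariance thus all lay below their simulated means. Whether the simulated noise matches that of the arrays was not tested. The gap is therefore no evidence that the mutants share less than unchanged genotypes would. The correlation was 0.311 within number 1 and 0.465 within number 2, where the wild-type array is shared, and 0.158 and -0.009 when nar1-4 was taken from one number and nbp35-3 from the other, so that no array was shared.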

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

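The direct test between the mutants was fixed before the data were examined, and the count of the same pattern over all probe sets was chosen only after these genes were seen. In 5 of the 23 genes named by smallest p, nar1-4 lay on one side of wild type and nbp35-3 on the other within both replicate numbers, and 6.9% of all probe sets (1567) did the same. All 5 were named by their p in the comparison between the mutants, which favours such a pattern. Among the list members named, which were not part of the 23, PRL lay at 0.03 and 0.32 in nar1-4 and at -0.25 and -0.68 in nbp35-3. AT2G41730 was 1.38 and 1.09 above wild type in nar1-4 within numbers 1 and 2, and -0.42 and -1.06 from it in nbp35-3, a difference between the mutants of -1.97 on the log2 scale. AT3G43110 differed by -0.40 and -0.12 in nar1-4 and by 0.35 and 0.66 in nbp35-3, 0.77 between the mutants. AT4G16920 differed by -0.17 and -0.31 in nar1-4 and by 0.52 and 0.28 in nbp35-3, 0.64 between them. AT2G32020 stood at 0.27 and 0.47 in nar1-4 and at -0.32 and -0.43 in nbp35-3, a difference of -0.74. AT2G32220 stood at 0.27 and 0.37 in nar1-4 and at -0.25 and -0.34 in nbp35-3, a difference of -0.61. In the direct limma test PRL and each of the 5 had a Benjamini-Hochberg adjusted p of 1, and with the replicate block the adjusted p was 0.211 for AT2G41730, 0.619 to 0.647 for the other 4 and 0.86 for PRL, so a difference between the mutants is not established for any of them.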

How the results depend on the processing

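Counts within each number, list membership by locus alone, lists of at least 3 members, correlations without a shared array, and the block combined with another setting were chosen only after results were seen. Under every planned setting 0 probe sets were called in each of the 3 comparisons and 0 in both mutants, including the replicate block, which changed no probe set call. Combined with the block, leaving out nbp35-3 replicate 1 gave 24 calls for nar1-4, 240 for nbp35-3, 105 between the mutants and 6 shared, and leaving out nbp35-3 replicate 2 gave 24, 14 and 63. By construction, a genotype left with 1 array adds nothing to the spread, so these fits have 1 residual degree of freedom and a prior of 6.28. In the comparisons with nbp35-3 the lone array is assumed to vary like the others. The comparison of nar1-4 with wild type does not use that array. With the block, leaving out a wild-type or a nar1-4 array gave no call in any comparison. Calls with the block thus appeared only where the array left out was of nbp35-3. Differences of at least 2-fold within both numbers, without a test, numbered 31, 9 and 30. The correlation of the mutants' fold changes was 0.003 (without nar1-4 replicate 1) to 0.849 (without wild-type replicate 1) when 1 array was left out, since the difference between the numbers then enters a genotype's mean, and 0.158 and -0.009 with no shared array. Lists called, 1 in nar1-4, 2 in nbp35-3 and 1 between the mutants, came to 0 in each with an estimated correlation, with fry and with the replicate block, the block with an estimated correlation or with lists of at least 3 members, and membership by locus alone with an estimated correlation. Median centring called 2 in nar1-4 and 4 in nbp35-3, quantile normalization 0 between the mutants, the filter on dim probe sets 2 in nar1-4 and 3 in nbp35-3, and lists of at least 3 members 0 in nar1-4 and 3 in nbp35-3, where oxidative stress and flavonoids were new (adjusted p = 0.0469 each, against 0.558 and 0.594 over all lists with an estimated correlation). Membership by locus alone called 2 in nar1-4, 3 in nbp35-3 and 1 between the mutants, and with the block 4, 3 and 2. In nbp35-3 these 3 were the 2 lists lost with the block alone and the flavonoid list (0.0385 each with the block, and 0 called with an estimated correlation). With 1 array left out the lists called were 0 to 3 in nar1-4, 1 to 4 in nbp35-3 and 1 to 4 between the mutants. The flavonoid list's median between the mutants lay between -0.433 (without nar1-4 replicate 1) and 0.460 (without nar1-4 replicate 2), and each of these 2 gave a camera call (adjusted p = 0.00233 and 2.59e-05), so calls hung on single arrays. Of these changes in lists the cause was not tested. Fold changes of named genes kept their direction and passed no test in 270 alternatives chosen beforehand. These do not include the block combined with a left-out array, where AT2G04050 and others passed with an nbp35-3 array left out. Medians of lists kept direction and call in 669, changed sign with no call in 57, gained a call in 25, lost one in 22, and changed sign with a call in 1. Median fold changes over all probe sets lay between -0.006 and 0.038 under each scaling. Alternatives for NAR1 and NBP35 were not run, since no probe set names them. With 2 arrays per genotype the number of arrays limits every comparison, and signal over background was not measured.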

Other observations

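Of the tests below, those on brightness and on the shifted nbp35-3 array were written before their results were seen, and those on gene lists between the numbers, on covariance and on neighbouring genes, as well as list membership by locus alone and the glutaredoxin genes, were chosen only after.

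The arrays of replicate number 1 and number 2 differed widely in each of the 3 genotypes, and the genes named here were chosen after their values were seen. In the limma fit with the replicate block, 2787 probe sets were higher and 2538 lower in number 2 with Benjamini-Hochberg adjustment, 1332 of them by at least 2-fold. COR27 differed by -5.17 ± 0.18 on the log2 scale (SE, adjusted p = 0.000591), with -5.60, -5.22 and -4.70 in wild type, nar1-4 and nbp35-3. The iron deficiency genes AT1G47400, written beforehand as IMA1, and BHLH101 were 4.21 ± 0.32 and 3.59 ± 0.40 higher (adjusted p = 0.00184 and 0.00443). BCAT4, which starts methionine-derived glucosinolate synthesis, was 3.16 ± 0.11 higher and the glutathione transferase GSTU20 2.93 ± 0.19 higher. GI, a clock gene with a strong daily rhythm, differed by -0.15 ± 0.13 (adjusted p = 0.471).

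In nbp35-3 and nar1-4 alike, 4 neighbouring glutaredoxin genes had higher means than wild type within both numbers. AT4G15680 was 3.47-fold, AT4G15660 1.98-fold, AT4G15690 2.04-fold and AT4G15700 1.99-fold higher in nbp35-3 (log2 SE 0.56, 0.33, 0.26 and 0.23), and in nar1-4 they were 1.97-fold, 1.64-fold, 1.41-fold and 1.8-fold higher. All had a limma adjusted p of 1, and 0.93 in nbp35-3 with the replicate block. Both comparisons share the wild-type arrays, so part of the likeness between the mutants comes from those arrays.

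With membership by locus alone, the oxidative stress list gained AT2G04050 and AT2G21640 and held 6 members with a median of 0.39 in nar1-4 and -0.59 between nbp35-3 and nar1-4. Its camera adjusted p was 9.1e-05 in nar1-4 (0.00249 with the replicate block, and adjusted p = 0.38 with an estimated correlation), against 0.534 with the 4 members matched by name. Between the mutants it was 6.99e-09 (2.06e-06 with the block, and adjusted p = 0.159 with an estimated correlation). The iron deficiency list likewise held 6 members, with a median of 0.78 in nar1-4 (adjusted p = 0.149, 0.00734 with the block, and 0.794 with an estimated correlation) and -0.89 between the mutants (0.0938, 0.000156 with the block, and 0.823 with an estimated correlation), and AT1G47400 and BHLH101 among them also differed by more than 3 log2 units between the numbers. Both lists were written before the data were examined, but the change of membership was made when AT2G04050 had been seen.

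The gap between the replicate numbers could come from hybridisation or scaling that depends on brightness alone, or from plants or harvests that differed between the numbers. Brightness, in 100 bins, accounted for 1.7% of the variance of the number 2 minus number 1 difference. RMA had already normalized the arrays together by quantiles, which removes differences of that kind, so the low share does not decide on the first. Of 11 lists with at least 3 measured members, 5 lay outside the central 95% of 10000 random lists matched on brightness. Their medians were 0.85 for iron deficiency, 0.60 for flavonoids, 0.47 for antioxidants, -0.56 for heat shock and -0.88 for jasmonate. Random lists do not hold genes regulated together, which any difference between arrays could move together. The count therefore does not decide between the explanations. The spikes were also brighter by 0.56 to 2.09 in number 2, and the 25S rRNA probe set was lower there (12.19 and 10.52 in wild type), so hybridisation or labelling differed between the numbers. The RNA input and harvest time of each number stay open, since the labels tie neither to a sample.

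The nbp35-3 differences from wild type correlated at -0.046 between the numbers, and those of nar1-4 at 0.214. The axis that separates the numbers was taken as nar1-4 replicate 1 minus replicate 2. The nbp35-3 differences correlated with this axis at 0.108 in number 1 and 0.331 in number 2, so replicate 2 lay towards number 1. With the axis regressed out, to remove such a shift of nbp35-3 replicate 2, the correlation between the numbers was -0.087. The covariance, which noise independent between arrays and genes would not lower, was -0.00751 with the axis regressed out (95% jackknife interval over 100 blocks of probe sets, -0.0112 to -0.0038) and -0.00421 without (-0.00801 to -0.000414), against 0.0166 in nar1-4 (0.0141 to 0.0191). These intervals cover probe sets and not arrays, each difference rests on 1 array per genotype, and nar1-4 of number 1 with nbp35-3 of number 2, which share no array, gave a covariance of 0.0145 (r = 0.158). The written bound on the correlation likewise assumed that single arrays vary less than this, so a shift of that array and noise shared by many genes both stay open. Also open are a sample that is not what its label says, which the unmeasured NBP35 transcript cannot settle, and a response of nbp35-3 that differs between the numbers, which was not tested and may be biological.

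Among the 18 named genes at least 2-fold from wild type in nar1-4 within both numbers, 1 pair lay within 3 genes of each other, AT1G72060 and AT1G72070, and 0.034 of 10000 random sets of named genes held as many. The pair was first noticed in this same set, so the count does not support any explanation of it, and whether the 2 genes respond together or are read through a shared transcript stays open, since they overlap in the gene table. AT1G72060 stood 1.38 ± 0.83 and AT1G72070 1.14 ± 0.58 above wild type. AT2G04070 was 1.55 ± 0.34 above wild type beside 3.22 for AT2G04050, but lay more than 3 genes away.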
